A study of Oikopleura dioica with 2 samples.

How the data were processed

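RNA was sequenced from unfertilized eggs and from larvae at 8 hours post-fertilization (hpf) of Oikopleura dioica, a planktonic tunicate that keeps a tadpole body plan throughout life. Per the labels' protocols, the animals descended over generations from a single pair, with eggs taken from 46 females and larvae raised from 63 adult pairs. Polyadenylated RNA was selected with oligo dT, and strand-specific paired-end libraries with an insert of 200 bp were read at 90 bp on an Illumina HiSeq instrument, also per the labels' protocols. The labels list 1 sample for each of the 2 stages, while the series' design text speaks of 2 biological replicates per stage.

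The deposited table holds 1 column of FPKM values (fragments per kilobase of transcript scaled to the library's mapped fragments) per stage, made by the authors with RSEM, a program that assigns reads to transcripts and estimates their abundance, per the submitters' processing notes. The version of RSEM, the assembler, any filter and the genome build are not given in the sources used here. The file's name speaks of log2 values, but the deposited FPKM values are linear, since they reach 26658 in eggs and 39446 in larvae and include exact zeros. Every value above 0 ends in 0 or 5 at the thousandths place, with 5 in 46.8% of the egg values and 49.4% of the larval values. That is what a mean of 2 values given to 2 decimals leaves, so each column was treated as the authors' mean over replicates. The columns carry no error, and the spread between replicates cannot be computed from them. No test of the stages was therefore possible: there is no p-value, SD or n in what follows, and every difference between stages is a difference between 2 deposited values with no replicate check. The linear FPKM values were used in place of the log2 values assumed when the design was fixed, which changed no rule. No column of another sample was present (0 unused columns).

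Each of the 57962 rows is an assembled component, the unit that the table calls a gene, with 86898 transcripts among them. Component identifiers were used exactly as deposited. None of them (0) matched the 17178 genes of the RefSeq gene table for assembly OKI2018_I68_1.0 used here, which identifies genes by other accessions, and the table gives no gene names, sequences or coordinates. The gene lists fixed before the data were examined could therefore not be filled and are not reported, and by the rule fixed for that case at most 2 identifiers per direction are named, those with the largest difference. Several components can be pieces, alleles or near-identical copies of 1 gene, so counts of components are not counts of genes. The table gives no read counts, so the depth of each library is unknown and no counting interval was computed for the FPKM values.

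Differences are larvae minus eggs on the log2(FPKM + 1) scale, with a pseudocount of 1 FPKM, which understates the change of low components. A component was called detected at 1 FPKM or more and stage-biased when the stages differed at least 4-fold (2 on the log2 scale). Both are rules of size, not tests. Components were also grouped by abundance (limits of 10, 100 and 1000 FPKM) and by their number of transcripts. A comparison by class of identifier was planned, but the classes by number of transcripts, like the abundance groups, were chosen after the table was seen. The median difference of each class with 2 or more transcripts was placed among the medians of 10000 random lists of the same size, matched on the mean log2 level in 20 bins, as a description of these libraries only. Correlations are across components, which are not independent replicates. Alternatives were other pseudocounts, detection limits and fold limits, a filter on low values, rescaling by a trimmed mean of log ratios (30% of ratios and 5% of abundances trimmed), by the upper quartile or by quantile normalization, rescaling each column to a sum of 1000000, and summing subcomponents. The last of these and the rescaling to 1000000 were chosen after seeing the data. The functions were tested on simulated data: with the egg values set against a scaled copy holding 200 planted 16-fold changes among the 57962 components, 100.0% of the changes were recovered with 0 false calls. The changes were planted only in well-expressed egg components, with small scatter between the copies. This checks the code and not the accuracy of the 4-fold calls, least of all at low levels. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.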

Results

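The transcriptomes of unfertilized eggs and of larvae at 8 hpf were compared to describe the maternal RNA stored in the egg and the RNA present after zygotic transcription has begun. Eggs carry RNA deposited by the mother, whereas larval RNA can be a mixture of remaining maternal and newly made zygotic transcripts. The table gave 1 value per stage for each of 57962 assembled components, of which 48629 held a single transcript and 9333 held 2 or more. The FPKM values summed to 1158185 in eggs and 1269958 in larvae. The read depth behind the values is not given in the table.

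Far more components were detected in larvae than in eggs. At 1 FPKM or more, 31666 components were detected in larvae and 10110 in eggs, a ratio of 3.13. Upper-quartile scaling lowered the larval count to 17058. Both stages shared 8919 components, which were 88.2% of those detected in eggs and 28.2% of those detected in larvae. The remaining 22747 larval components were below 1 FPKM in eggs, and 18484 of these were listed at 0 there. In the opposite direction, 1191 components were detected in eggs only, 746 of them listed at 0 in larvae. Larva-only components had a median of 5.62 FPKM in larvae (interquartile range 2.68 to 15.8) and together held 34.5% of the larval FPKM. Egg-only components had a median of 6.20 FPKM in eggs and held 2.34% of the egg FPKM, so nearly all of the egg signal (97.5%) came from components also detected in larvae. A further 24191 components were listed at 0 in both stages.

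As deposited, the excess of larval components lay at low and middle levels. At a limit of 10 FPKM, 13306 components were detected in larvae and 6583 in eggs, an order that turned around after upper-quartile scaling (1929 in larvae) and was lost by construction under quantile normalization (8791 in each stage). At 100 FPKM the counts were 1072 in larvae and 1227 in eggs, and at 1000 FPKM they were 141 and 176. This order at 100 and 1000 FPKM turned around when the larval values were rescaled by the trimmed mean of log ratios, which gave 2329 and 210 larval components. Among components above 0, egg levels were spread broadly, with quartiles of 0.565 and 37.3 FPKM, whereas larval levels lay between narrower quartiles of 2.81 and 19.0 FPKM. These are different sets, of 14660 components in eggs and 32994 in larvae. Larvae also had almost no values below 0.1 FPKM, as 32984 components reached it, against 13281 in eggs. Part of the narrower larval spread may thus come from the assembly, a filter or depth.

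**Figure D1:**
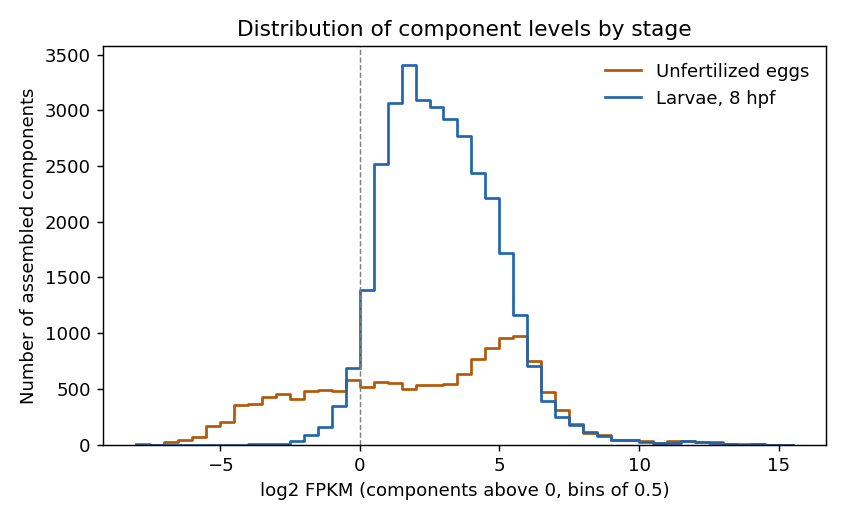
Number of assembled components (vertical axis) by log2 FPKM in bins of 0.5 (horizontal axis), for components above 0 in eggs (brown line) and in larvae at 8 hpf (blue line), with the dashed line at 1 FPKM. Larvae have 31666 components at or above that line and eggs have 10110.

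Most stage-biased components were higher in larvae. On the log2(FPKM + 1) scale, 16667 components were at least 4-fold higher in larvae and 2550 were at least 4-fold higher in eggs, so that 86.7% of the differences of this size favoured larvae. This split depended on scaling: it was 93.8% after trimmed mean scaling, 51.3% after quantile normalization and 41.0% after upper-quartile scaling. The 2 directions differed in the level of the other stage. Of the components higher in larvae, 95.1% were below 1 FPKM in eggs, against 29.6% of the components higher in eggs that were below 1 FPKM in larvae. These shares follow in part from the rule. With the pseudocount of 1 FPKM, a 4-fold call on a low component requires less than 1 FPKM in the other stage. Of the calls toward larvae, 7960 were at 1 to 10 FPKM in larvae. They also follow from detection, as 10110 of all 57962 components reached 1 FPKM in eggs and 31666 in larvae. The larva-biased components had a median larval level of 10.7 FPKM. The egg-biased components had a median of 54.4 FPKM in eggs and of 6.23 FPKM in larvae, so most remained detectable at 8 hpf. Among the 8919 shared components, 68.2% were lower in larvae, with a median difference of -0.70 (interquartile range -1.78 to 0.38), which became 0.04 after trimmed mean scaling, -1.26 after quantile normalization and -3.03 after upper-quartile scaling.

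The component with the largest difference toward larvae was comp19631_c0, at 4.815 FPKM in eggs and 17936 FPKM in larvae, a difference of 11.59 on the log2 scale. The next was comp20349_c0, at 15.6 FPKM in eggs and 39446 FPKM in larvae (11.21), which made it the most abundant component of the larval libraries with 3.11% of their FPKM. The largest difference toward eggs was that of comp28019_c2, at 5881 FPKM in eggs and 6.11 FPKM in larvae (-9.69), followed by comp28545_c0, at 763 FPKM in eggs and 0.505 FPKM in larvae (-8.99). These 4 differences kept their sign under each pseudocount and scaling tried, but not their order. With a pseudocount of 0.1 FPKM, comp28545_c0 (-10.30) passed comp28019_c2 (-9.89). With a pseudocount of 10 FPKM, comp20349_c0 (10.59) passed comp19631_c0 (10.24), as it also did after quantile normalization (10.53 against 10.41). The most abundant egg component, at 26658 FPKM, was at 111 FPKM in larvae.

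The median difference varied among groups of components classed by their egg level. Components of 100 to 1000 FPKM in eggs had the lowest median of the egg groups as deposited, with a median difference of -2.20 (interquartile range -3.23 to -1.42) over 1051 components, a 4.60-fold lower level. Of these, 608 (57.8%) were at least 4-fold lower in larvae and 2 at least 4-fold higher. The 608 became 351 after trimmed mean scaling and 1039 after upper-quartile scaling. The 5356 components of 10 to 100 FPKM in eggs had a median difference of -1.36, and the 3527 of 1 to 10 FPKM one of 0.29, which turned to -1.19 after upper-quartile scaling and -2.01 after quantile normalization. Under quantile normalization the groups of 10 to 100 and 100 to 1000 FPKM were level, at -2.27 and -2.26. The 176 components of 1000 FPKM or more in eggs had a median difference of only -0.32, although 66 of them (37.5%) were at least 4-fold lower in larvae. The 176 include 77 components that were nearly equal in both stages, described below, and none (0) of these was at least 4-fold lower. All 66 thus lay among the other components, where their share was no smaller than the 57.8% of the 100 to 1000 FPKM group. After trimmed mean scaling the median of the group of 1000 FPKM or more changed sign, to 0.52, with 37 components at least 4-fold lower. It was -3.01 after upper-quartile scaling, with 173. Under trimmed mean scaling the medians of the 10 to 100 and 100 to 1000 FPKM groups stayed negative, at -0.57 and -1.38.

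Abundant larval transcripts were often nearly missing from eggs. Of the 1072 components at 100 FPKM or more in larvae, 707 (66.0%) were at least 4-fold higher than in eggs, and 560 (52.2%) were below 1 FPKM in eggs, including 151 listed at 0. This is not particular to abundant components: of all 31666 detected in larvae, 22747 were below 1 FPKM in eggs, a larger share. Of the 1227 components at 100 FPKM or more in eggs, 674 (54.9%) were at least 4-fold lower in larvae, but 38 (3.10%) were below 1 FPKM there. The 674 became 388 after trimmed mean scaling and 1212 after upper-quartile scaling. The larval components of 100 to 1000 FPKM had a median difference of 6.69 (interquartile range 1.07 to 7.46), which was 3.68 with a pseudocount of 10 FPKM and 4.07 after upper-quartile scaling. The 141 larval components of 1000 FPKM or more had a median difference of -0.02 (interquartile range -0.12 to 9.16). It became 0.83 after trimmed mean scaling and -2.70 after upper-quartile scaling. These 141 also include the 77 near-equal components, which largely set that median. Outside the 77 lay all 41 components that were at least 4-fold higher in larvae, so the median does not describe the class as a whole.

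**Figure D2:**
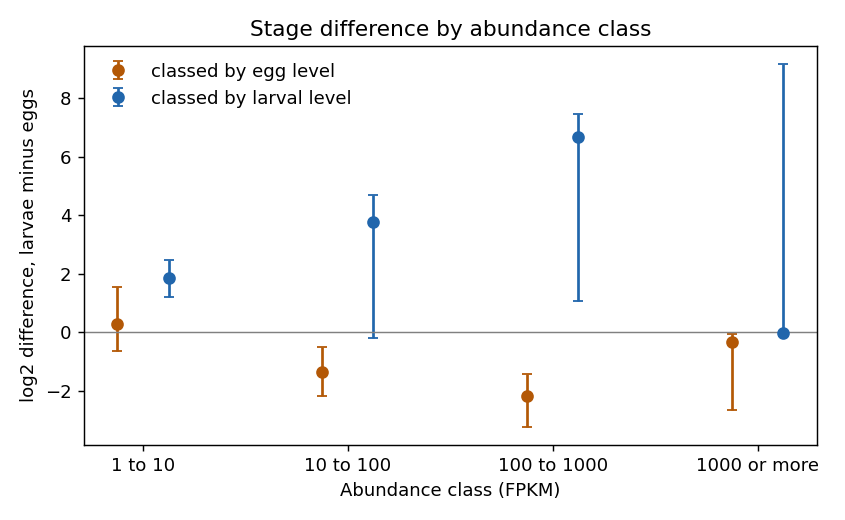
Median log2 difference, larvae minus eggs on the log2(FPKM + 1) scale (vertical axis), by abundance class in FPKM (horizontal axis), with components classed by their egg level (brown) or their larval level (blue), and bars spanning the interquartile range over components, which is not a replicate error. The egg class of 100 to 1000 FPKM lies at -2.20 and the larval class of 100 to 1000 FPKM at 6.69, while both classes of 1000 FPKM or more have medians near 0 as deposited (-0.32 and -0.02), which become 0.52 and 0.83 after trimmed mean scaling. Both classes of 1000 FPKM or more include the 77 near-equal components, which draw their deposited medians toward 0.

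The top of the abundance range was largely common to both stages. The 100 most abundant components held 49.1% of the FPKM in eggs and 44.0% in larvae, and 77 components were in both lists. These 77 components had nearly equal deposited levels in the stages, with medians of 4612 FPKM in eggs and 4719 FPKM in larvae. Their median difference was -0.06 (interquartile range -0.14 to -0.01), and 76 of the 77 differed by less than 2-fold. After trimmed mean scaling the median was 0.78, and after upper-quartile scaling it was -2.75, with 76 of the 77 at least 4-fold lower in larvae. Their interquartile range stayed narrow under both, at 0.71 to 0.83 and -2.82 to -2.70. By contrast, the 23 components in the egg list alone had a median difference of -2.83 and 18 of them were at least 4-fold lower in larvae, which became 11 after trimmed mean and 23 after upper-quartile scaling. The 23 in the larval list alone had a median difference of 9.38 (interquartile range 0.73 to 10.55). Of these, 15 were at least 4-fold higher in larvae, 6 were within 2-fold and 12 were below 10 FPKM in eggs. Upper-quartile scaling gave a median of 6.69, with 15 at least 4-fold higher in larvae and 6 at least 4-fold higher in eggs. Further down, 307 of the 1000 most abundant components were common to both stages. Across all components the log2(FPKM + 1) values of eggs and larvae correlated with Pearson's r of 0.45 and Spearman's rho of 0.50, and across the 8919 shared components with 0.56 and 0.49.

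**Figure D3:**
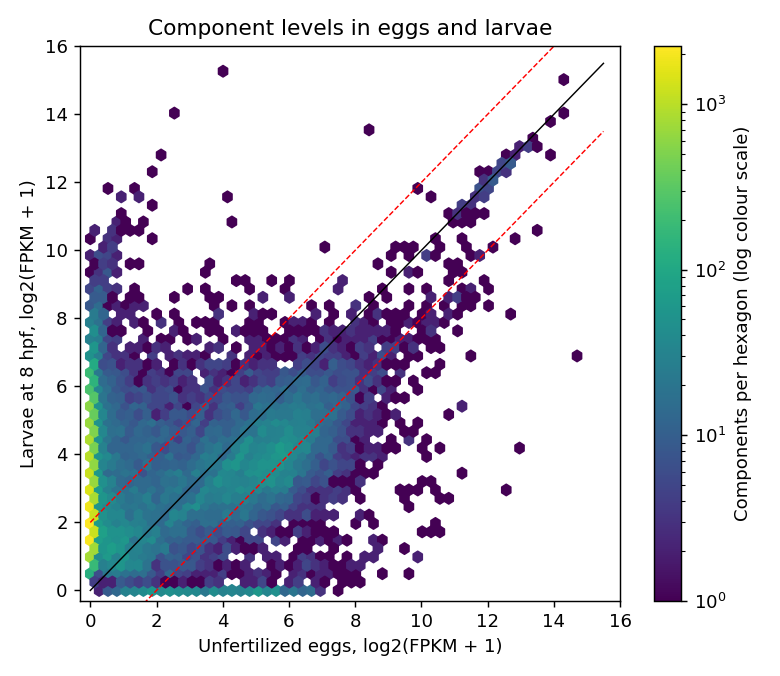
Level of each component above 0 in at least 1 stage, as log2(FPKM + 1) in eggs (horizontal axis) and in larvae (vertical axis), with colour giving the number of components per hexagon on a log scale, the solid line marking equal levels and the dashed lines a 4-fold difference. A narrow streak along the line of equality at the top holds most of the 77 components in both top 100 lists, apart from the broad cloud of shared components below the line and the column at 0 in eggs, which includes 18484 components of 1 FPKM or more in larvae.

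Components with several transcripts were more often detected than those with 1, in both stages. Of the 4132 components with 3 or more transcripts, 98.0% were detected in larvae and 42.4% in eggs. For the 5201 components with 2 transcripts the shares were 88.8% and 34.4%, and for the 48629 with 1 transcript they were 47.3% and 13.5%. The class with 3 or more transcripts had a median difference of 2.85 and lay above all of the 10000 random lists matched on mean level (2.25 to 2.68). The class with 2 transcripts had a median difference of 1.91 and lay at percentile 2.07 of its matched lists, below their median of 1.97. Both medians depended on scaling. For 3 or more transcripts the median was 0.86 after upper-quartile scaling and 0.72 after quantile normalization. For 2 transcripts it was 0.42 and 0.11. The matched lists were not drawn again under these scalings. The number of transcripts comes from the assembly, which is not described in the sources used here. If these reads were used to build it, that number can itself depend on the reads of each stage. The detection shares and the place among matched lists are then not separate from the assembly, which was not tested. The single-transcript class had a median of 0, since 48.8% of it was listed at 0 in both stages.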

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

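No paired analysis was possible because each stage has 1 column, a mean with no replicate number, and for the same reason no replicate could be left out. Summing transcripts to genes was not run, since the table already has 1 row per component, and the median differences of the gene lists could not be computed without names. The alternatives chosen after seeing the data were the sum over subcomponents, the rescaling to 1000000 and the scalings of the detection counts. A filter at 1 FPKM left both counts of stage-biased components at their values by construction. With the deposited scaling, detection was higher in larvae at the limits of 0.1, 1 and 10 FPKM, but at 10 FPKM upper-quartile scaling left 1929 larval against 6583 egg components. The limit of 10 FPKM lowered the counts to 6583 in eggs and 13306 in larvae, and upper-quartile scaling lowered the larval count at 1 FPKM to 17058. The counts of components at least 4-fold higher in larvae and in eggs were 3401 and 1057 with a pseudocount of 10 FPKM, 4734 and 6811 after upper-quartile scaling, 6526 and 6186 after quantile normalization, and 10161 and 1043 at an 8-fold limit. Trimmed mean scaling lowered the egg-biased count to 1430 and a 2-fold limit raised it to 4880. The order of the 2 directions turned around under upper-quartile scaling alone. Upper-quartile scaling lowers every larval value 6.44-fold, because most components are at or near 0 in eggs, and trimmed mean scaling raises every larval value 1.80-fold. Quantile normalization moved the median difference of all components to -0.81. The correlation of 0.45 was 0.45 with a pseudocount of 0.1 FPKM, 0.56 over components detected in both stages and 0.50 as Spearman's rho. The top 10 components held 12.9% of the FPKM in eggs and 13.2% in larvae, and the top 1000 held 78.1% and 65.7%. For components with 1 transcript the median difference moved from 0 to -0.81 after quantile normalization and to 1.93 over detected components. For those with 2 transcripts it was 4.24 and 0.43 with pseudocounts of 0.1 and 10 FPKM, 2.60 after trimmed mean, 0.42 after upper-quartile and 0.11 after quantile scaling, 2.16 over detected components, 1.56 with subcomponents summed and 1.68 after rescaling to 1000000. For those with 3 or more transcripts the same settings gave 4.88, 0.92, 3.62, 0.86, 0.72, 2.88, 2.78 and 2.58. The 24 alternatives of the 4 named components gave 0 changes of sign.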

Other observations

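The tests of library depth, of abundant egg components and of carried-over egg RNA were chosen only after the results they bear on were seen. Single transcripts made up 76.9% of the larva-only components, 61.7% of the shared ones and 89.9% of the egg-only ones. Of the 77 components in both top 100 lists, 71 had a single transcript, against 17 of the 23 in the egg list alone and 12 of the 23 in the larval list alone. The 77 components carried 38.7% of the egg FPKM and 33.8% of the larval FPKM. The 23 of the larval list alone carried 10.2% of the larval FPKM and 1.42% of the egg FPKM.

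Why larvae had about 3.13 times as many detected components as eggs was weighed first. Components with a read rise at most in proportion to reads, so deeper larval libraries would need at least the 2.25-fold excess of components above 0. Among 427 single-transcript components between 0.4 and 1.5 FPKM in both stages, the larva-to-egg ratios clustered in steps, and a larval depth more than 2 times that of eggs would add steps between the main step and its double, each at least as full as the double. Between them lay 60 components, against 122 and 91 within 10% of each. The share between was 39.7% of the 151 in that interval and at the double (95% Wilson interval 32.3% to 47.7%, for counting error only). This argues against depth as the whole cause only if values in this range are a few whole reads, which was not checked. The smallest values above 0 were 0.005 FPKM in eggs and 0.065 FPKM in larvae, and lengths are unknown. Egg values in this range therefore need not be so few reads. Of the components above 0, 32984 of 32994 reached 0.1 FPKM in larvae, against 13281 of 14660 in eggs. With deeper larval libraries alone, the lowest values should lie in larvae, so this direction goes against depth. It does not settle the question, since values near the floor also depend on the assembly and any filter. The step rule itself was tried only on simulated whole reads. Abundant components taking more of the egg reads stay open as a part of the cause, since the top 1000 left 1.57 times as large a share of FPKM in larvae, below the 2.25-fold needed, but shares of FPKM are not shares of reads and the lengths are not known. Zygotic transcription, pieces of longer transcripts, unspliced RNA and RNA of other organisms in the culture cannot be told apart here, because the components carry no sequence or name, and the 76.9% share of single transcripts among larva-only components does not decide between them. The components that can be detected also depend on the assembly and any filter, which are not given. Of the components above 0, 31666 of 32994 reached 1 FPKM in larvae, against 10110 of 14660 in eggs. The part that the assembly or a filter has in the excess cannot be judged.

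The 77 components at nearly equal deposited levels were weighed next. Their median absolute difference of 0.10 on the log2 scale was below the lowest value, 0.30, from 10000 shuffles of the larval values among the same components, so being abundant in both stages does not by itself account for it. Egg RNA carried into the larval libraries would keep the other abundant egg components near their egg level too, yet 66 of the 176 components at 1000 FPKM or more in eggs were at least 4-fold lower in larvae. That count depended on scaling, with 37 after trimmed mean and 173 after upper-quartile scaling. The closeness to 0 holds for the deposited scale, while the narrow spread within the 77 does not depend on a scaling factor. Their identity is not known from the table, no biological explanation was tested, and neither was a common source of these reads in all libraries.

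The lower larval level of egg components of 100 to 1000 FPKM, compared with those of 1000 FPKM or more, could come from choosing components by their egg value. Classed instead by the mean of both stages, the 462 components of 100 to 1000 FPKM had a median difference of -1.50 (95% bootstrap interval over components -1.66 to -1.30), below the -0.11 (-0.16 to -0.07) of the 119 components of 1000 FPKM or more. The choice by egg value is therefore not the whole of the contrast of medians. A single scaling factor would shift both classes by the same amount. Dilution of stored RNA by a common factor is such a shift and does not give the contrast either. The contrast is, however, not separate from the 77 near-equal components. All of them lay in the top class by either choice, with at least 2560 FPKM in eggs and 2209 FPKM in larvae. They made up 77 of its 119 members by mean level and so largely set its median. None of them (0) was at least 4-fold lower in larvae. The median of the other top components was not computed. Classed by the mean, 15 of the 119 top components were at least 4-fold lower in larvae, all outside the 77. In the middle class 165 of 462 were. Classed by egg level, the counts were 66 of 176, again all outside the 77, and 608 of 1051. As deposited, the share at least 4-fold lower was thus no smaller among the other top components than in the middle class. The contrast therefore does not show a difference between the classes at large. Loss of transcripts in the middle class and new synthesis in the top class were not tested.

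The 24191 components listed at 0 in both stages were 41.7% of the table. A single transcript was listed for 98.1% of them, against 73.7% of the other components. The smallest values above 0 were 0.005 FPKM in eggs and 0.065 FPKM in larvae.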
